A study of Mus musculus with 6 samples.

How the data were processed

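The labels describe RNA sequencing of 6 mouse early round spermatid samples, 3 per genotype, from unstranded libraries. Per the labels' protocols, RNA was extracted with Trizol from testes or sorted cells, and libraries followed Illumina's standard procedure. Per the submitters' processing notes, the tools were TopHat, a spliced read aligner, and Cufflinks, a program that assembles and quantifies transcripts, and the genome build was mm9. Their versions, roles and settings are not given in the sources used here.

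The series has a single table, with an Ensembl gene identifier, a symbol and 6 value columns per gene and no header line. Its unit is not stated. A value column can be assigned to a sample only by its name, and these columns have none. On inspection, the rows were ordered by the ratio of the mean of the last 3 value columns to the mean of the first 3, which points to a division into 2 sets but names no genotype. Placing the columns by their order would assume an order of samples that no source used here gives. Placing them by the level of the targeted gene would take a measured value as the label, and that gene could then no longer check the labels. The 6 value columns were inspected when the table was first opened, which is how the row order was found, and were used for no result, and no test between genotypes, replicate comparison, depth or normalization is reported. The planned tests on expression values were not run. Some entries may have been left out of the copy used here, so a gene with no row is described only as not listed.

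The identifier and symbol columns were compared with the GENCODE M21 mouse annotation (build GRCm38), used for names and gene classes only and never for coordinates. Of the 10913 rows, 10759 matched by identifier, 88 by a symbol that names one gene, and 66 by neither. The 21 gene lists, 6 of them markers of other testis cell types, were fixed before the data were examined. Members were resolved to protein-coding genes by symbol or by RefSeq synonym, and members that could not be resolved to a single gene were left out. Those left out were Ddit3, Mx2, Hbb-b1, Hbb-b2 and Asty. The lists of ribosomal protein, mitochondrially encoded and respiratory chain genes were defined by symbol pattern instead, and there every matching gene counted, including both genes that share the symbol Atp5o. The rule for named genes depended on expression tests and could not be applied. The genes named are members of the fixed lists, chosen after seeing whether they had a row.

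Each list of at least 5 members was compared with all other protein-coding genes by a two-sided Fisher's exact test (scipy 1.17.1, Python 3.11.15), with Benjamini-Hochberg adjustment over the 21 lists and a threshold of 0.05. This test replaces the planned tests and was chosen after the table was seen. Intervals of shares are exact (Clopper-Pearson) 95% binomial intervals. The authors' own annotation and listing rule are not given in the sources used here. The list members and the comparison genes may therefore include genes that could not have entered the table. The test was tried first on simulated lists, drawn at random from all protein-coding genes or mostly from listed ones. Their genes were drawn independently, so the trial checked the calculation only and not its behaviour on lists of related genes. The 3 alternatives left out receptor genes, kept only genes with a RefSeq entry (found by gene identifier or symbol), or matched rows by identifier only. A gene whose RefSeq entry has another symbol and no matching identifier would also drop out of the RefSeq setting.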

Results

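RNA was profiled by sequencing in early round spermatids, the haploid germ cells that follow meiosis in the mouse testis. The 6 samples fell into 2 genotypes on a mixed strain background, with 3 Miwi+/- samples and 3 Miwi-/- samples. Miwi is another name of Piwil1, which encodes a PIWI protein that binds pachytene piRNAs, the small RNAs made in large amounts by meiotic and postmeiotic male germ cells. The design asks which transcripts differ between spermatids of mice with and of mice without an intact copy of this gene. That comparison was not made here. The 6 value columns of the series table carry no names in the table used here, so no column could be tied to a sample or to a genotype, and neither the order of the columns nor the level of Piwil1 was taken as a substitute. No expression level, fold change or depth is therefore given for any gene. The results are limited to which genes the table lists.

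The table listed 10913 genes, each with an Ensembl identifier and a symbol. The rows that matched the reference annotation stood for 10828 distinct genes of it. Of these reference genes, 10583 were protein-coding, which is 48.2% of the annotation's 21951 protein-coding genes. Piwil1, the targeted gene, was listed as ENSMUSG00000029423. The rule by which genes entered the table is not given in the sources used here. A listed gene is a gene that has a row for the series as a whole. Whether listing depended on genotype is not known, and a gene without a row is not shown to be unexpressed.

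The lists for the acrosome, the sperm tail, spermatid regulators and the piRNA pathway were each listed more often than other protein-coding genes. All 23 members of the acrosome list had a row, among them Acr, the acrosomal protease acrosin, and Izumo1, a sperm protein needed for fusion with the egg (exact adjusted p = 3.57e-07). The sperm tail list had 27 of 28 members, including Odf1 of the outer dense fibres, Akap4 of the fibrous sheath and the CatSper calcium channel subunits Catsper1 to Catsper4 (exact adjusted p = 3.57e-07), and Tcte3 had no row. The list of spermatid regulators of transcription and translation had 21 of 22 members (exact adjusted p = 1.31e-05). These included Crem, a transcription factor of postmeiotic genes, its coactivator Fhl5, and Ybx2, a germ cell protein that binds stored mRNAs. The piRNA pathway and chromatoid body list had 23 of 25 members (92%, exact 95% interval 74.0 to 99.0%, exact adjusted p = 2.16e-05). Besides Piwil1 it included Piwil2, the helicase Ddx4, Mael and Tdrd6, a scaffold of the chromatoid body. Piwil4 and Tdrd5 were the members with no row. The p-values come from a two-sided Fisher's exact test on genes, which are not independent replicates, with Benjamini-Hochberg adjustment over 21 lists. The excess was not particular to these spermatid lists. The lists of mRNA decay factors (19 of 20) and nuclear-encoded respiratory chain genes (79 of 88) also passed.

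The protamine genes Prm1 and Prm2, whose products package sperm DNA, the transition protein genes Tnp1 and Tnp2, whose products act in the condensing spermatid nucleus, and Prm3 all had rows. The list that holds them, with spermatid histones, had 10 of 13 members, and its excess over other genes did not pass the test (exact adjusted p = 0.0882). It passed when only genes matched to a RefSeq entry were kept, which left 6 members, all of them listed (exact adjusted p = 0.0294). The 3 members with no row, H2afb1, H2afb2 and H2afb3, were left out there, along with some listed members. That pass therefore covers no unlisted member and does not bear on the full list. The list of sex-linked multicopy spermatid genes had 4 of 12 members, a share that did not differ detectably from that of other genes (33.3%, exact 95% interval 9.93 to 65.1%, exact adjusted p = 0.483). Cypt1 to Cypt4 were listed, while Slx, Slxl1, Sly, Ssty1 and Ssty2 were not. Whether these multicopy genes could have entered the table is not known, since the authors' annotation and listing rule are not given.

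**Figure D1:**
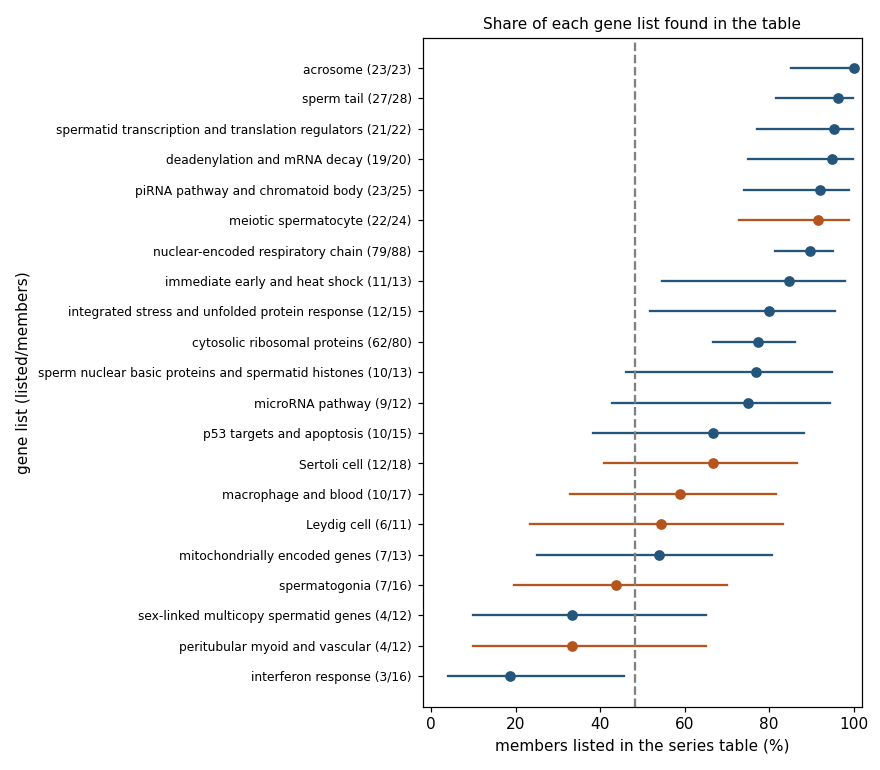
Share of the members of each gene list that have a row in the series table (x axis, %), for 21 lists (y axis, members listed over members). Points are shares, bars are exact 95% binomial intervals, orange marks lists of other testis cell types, blue marks all other lists, and the dashed line is the 48.2% of all protein-coding genes; the acrosome list lies at 100% and the interferon response list at 18.8%.

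Of the 6 lists for other cells of the testis, the meiotic spermatocyte list passed the test for more frequent listing. It had 22 of 24 members (exact adjusted p = 3.20e-05), including Sycp1 and Sycp3 of the synaptonemal complex and Spo11, which makes meiotic DNA breaks. Dmc1 and Rad21l had no row. The remaining lists did not pass the test, and differences between lists were not tested. The spermatogonia list had 7 of 16 members (43.8%, exact 95% interval 19.8 to 70.1%, exact adjusted p = 0.806). Gfra1, Id4 and Dmrt1 were among those listed, and Kit, Stra8 and Zbtb16 were among those not listed. The Sertoli cell list had 12 of 18 (exact adjusted p = 0.235), with Clu and Cst9 listed and Sox9, Wt1 and Fshr not. The Leydig cell list had 6 of 11 (exact adjusted p = 0.806), with the steroidogenic genes Cyp11a1, Cyp17a1 and Star listed and Insl3 and Lhcgr not. The macrophage and blood list had 10 of 17 (exact adjusted p = 0.547). The complement genes C1qa, C1qb and C1qc and the lysozyme gene Lyz2 were listed, and Ptprc, Csf1r, Hba-a1, Hba-a2 and Alas2 were not. The peritubular myoid and vascular list had 4 of 12 (exact adjusted p = 0.483), with Acta2 and Tagln listed and Pecam1 and Cdh5 not.

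The interferon response list passed the test for less frequent listing than other genes, with 3 of 16 members (18.8%, exact 95% interval 4.05 to 45.6%, exact adjusted p = 0.043). Isg15, Irf7, Ifit1 and Oas1a, genes induced by interferon, were among the members with no row. In the list of the integrated stress and unfolded protein responses, Ddit3 could not be resolved to a single gene and was left out. Of the remaining 15 members, 12 had a row (exact adjusted p = 0.0375). The endoplasmic reticulum chaperone gene Hspa5 and the transcription factor gene Atf4 were among them, and Atf3 and Trib3 were not. This excess did not pass when olfactory and vomeronasal receptor genes were left out of the comparison genes (exact adjusted p = 0.0695). The immediate early and heat shock list had 11 of 13 members (exact adjusted p = 0.0245), including Fos, Jun and Egr1. The p53 target and apoptosis list had 10 of 15 (exact adjusted p = 0.277), with Cdkn1a and Mdm2 listed.

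The list of deadenylation and mRNA decay factors had 19 of 20 members (exact adjusted p = 3.20e-05), including Cnot1 and Cnot7 of the CCR4-NOT deadenylase, and Dcp2 had no row. The microRNA pathway list had 9 of 12 (exact adjusted p = 0.134), and Ago1, Dicer1 and Drosha had no row. Of the nuclear-encoded respiratory chain list, which was defined by symbol and also holds assembly factors such as Ndufaf1, 79 of 88 genes were listed (exact adjusted p = 3.47e-15), and of the cytosolic ribosomal protein genes 62 of 80 (exact adjusted p = 5.95e-07). Rpl13, Rpl41, Rps24 and Rps4x, which most cells express, were among the ribosomal protein genes with no row. The mitochondrially encoded genes had 7 of 13 (exact adjusted p = 0.806), with mt-Co1 and mt-Cytb listed and mt-Co2 and mt-Co3 not.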

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

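All 3 alternatives were chosen after the table was seen. In the main setting, 10 lists passed the test for more frequent listing and 1 for less frequent. Leaving out olfactory and vomeronasal receptor genes gave 9 and 1, and keeping genes with a RefSeq entry gave 11 and 1. Matching by gene identifier only gave 10 and 1. The list that no longer passed without receptor genes was that of the integrated stress and unfolded protein responses, whose odds ratio went from 4.3 to 3.76. The list gained with RefSeq genes was that of sperm nuclear basic proteins and spermatid histones. It went from 10 of 13 members listed (exact adjusted p = 0.0882) to 6 of 6 (exact adjusted p = 0.0294). Members not matched to a RefSeq entry by identifier or symbol dropped out, among them every unlisted member and some listed ones. This pass therefore does not bear on the full list. No mitochondrially encoded gene list could be tested there. None of the lists with a finite odds ratio changed direction under these alternatives. Changes of setting that act on expression values (pseudocount, filter on low values, rescaling, quantile normalization, sample weights, leaving out each replicate) were not run, since they need expression values tied to samples. No paired analysis was possible because the value columns carry no replicate numbers. Depth was not assessed, since the unit of the values is not stated and they were used for no result.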

Other observations

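Shares were also taken for gene families picked by symbol after the lists had been examined. Of the olfactory receptor genes, which serve odour detection in the nose, 16 of 1135 had a row (1.41%), and of the vomeronasal receptor genes 3 of 329. Keratin genes had 6 of 53 and beta-defensin genes 11 of 42. At the other end, all 6 testis-specific serine kinase genes, all 10 CatSper subunit genes and all 5 tektin genes had a row. Of these, 5 of the kinase genes, 4 of the CatSper genes and all 5 tektin genes are members of the lists already described. ADAM protease genes had 25 of 33, proteasome subunit genes 36 of 40, solute carrier genes 179 of 371 and zinc finger genes named Zfp 209 of 394. These shares were not tested.

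Besides protein-coding genes, the distinct reference genes matched included 66 processed pseudogenes, 55 long intergenic noncoding RNA genes and 40 antisense genes. In unstranded libraries, reads of an antisense gene and of the gene on the opposite strand cannot be separated where they overlap.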
